A study of Mus musculus with 4 samples.

How the data were processed

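Expression was measured in mouse C2C12 myoblasts held in G0 for 48 hours in methyl cellulose suspension, on 2 arrays of control cells and 2 of cells given Wnt3A at 50 ng/ml. Groups and replicate numbers come from the sample titles and the treatment label, and the 4 columns of the value table were matched to samples by name. The protocol text is the same for all samples and mentions Wnt3A for the controls too, so the group was taken from the treatment label and the title. RNA was isolated with Trizol and labelled by the Affymetrix protocol, per the labels' protocols. The authors deposited 1 value per probe set and array; GCOS and PLIER are named in the submitters' processing notes, with no version and no role. The normalization, any filter, the scan dates and the genome build are not given in the sources used here. The deposited values were taken as log2 signals: their base is not stated, and it was read from the values, which run from 0.50 to 13.23 as log2 of a scanner signal would. A different base would rescale every difference and fold given here. The table gives no detection calls, so dim genes could only be judged by their signal. How the values were centred is unknown; the medians of the columns were 4.19, 4.20, 4.22 and 4.15 for control replicates 1 and 2 and Wnt3A replicates 1 and 2. As these lie within 0.5, nothing was normalized again.

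The table holds 22690 probe sets, of which 64 are array controls. Gene names came from the platform annotation given with the series, which lists 21084 of them. Of these, 691 name several genes and were not named, and 20380 with 1 symbol were used; 20351 of those were matched by Entrez ID to the symbols of the RefSeq annotation of assembly GRCm38.p6. Another 1555 probe sets outside the controls are not listed and are unnamed here. No coordinates are printed, since no build is named. A gene was represented by its probe set of highest mean over the 4 arrays, which gave 12393 genes. The lowest 25% by that mean, under a signal of 2.18, were left out, and 9294 genes were tested. Of the named tested genes, 62 had several probe sets above the limit, and in 7 of them these differed in sign. Tcf7 was not analysed here.

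Differences were tested in R 4.3.3 with limma 3.58.1, by lmFit and eBayes with an intensity trend, two-sided, on all 4 arrays with the group as the only term. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. Standard errors and 95% confidence intervals are those of the moderated fit, with 4.68 degrees of freedom. A count of genes at least 2-fold apart, with both Wnt3A arrays beyond both controls, is a description with no test. For 30 gene lists, 824 of whose 906 entries were on the array, camera was run with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; a list needed 5 tested members. Members were also adjusted over the list alone. Lists overlap, with 26 genes in 2 or more. The labels call the replicates biological but do not say whether cultures were started apart. P-values of single genes therefore measure the spread between these arrays. Those of camera compare the members of a list with the other genes, at a correlation that is preset and not measured. Estimated correlations within lists ran from -0.09 (Wnt feedback) to 0.91 (glycolysis and hypoxia).

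The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes per direction with the widest difference among those past the threshold. As none passed, the places went to the genes of lowest unadjusted p among those at least 2-fold apart. It also took up to 4 members per list by lowest p, and 21 genes of Wnt signalling, myogenesis and the cell cycle named in any case, of which 20 were on the array and 18 were tested. Clones and predicted genes were counted and not named.

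The procedure was tested on simulated data with the means and moderated spreads of the 9294 genes of the comparison of Wnt3A with control. There were 10 simulations of 200 changed genes each. Genes were drawn independently, with normal noise and no effect of the replicate number. Their spreads were already moderated, and so vary less between genes than the measured ones. Together this makes the simulated data easier than the real ones. At a log2 difference of 1 it recovered 17.6% of changed genes, at 2 it recovered 91.6%, at 4 it recovered 99.0% and at 6 it recovered 100.0%. Of its calls 6.75% were false. A list shifted by 0.5 was called in 10 of the 10 simulations, and unshifted lists were called 1 time in all. As the simulated genes were independent, this cannot show how the list test behaves with correlated genes. Nor do the recovered shares carry over to the real arrays. There Tnfrsf11b, with a log2 difference of 6.88, and Col8a1, with 5.39, did not pass over all genes.

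The alternatives tried were the replicate number as a block, quantile normalization, median centring, no filter on dim genes and the dimmer 50% left out. Others were the mean of a gene's probe sets or every probe set by itself, and a fit with no trend or with robust variance. Unmoderated statistics, a test against a 1.2-fold change, an adjusted p of 0.10 and each array left out in turn were also tried. A fit with 1 array left out has 1 array in a group, so its spread comes from the other group alone. Its p-values show how a call depends on an array and give no support of their own. Lists were also tested with an estimated correlation, with fry, and against 10000 random lists matched on mean signal. Scaling each array to its hybridization controls, and setting dim values to the filter limit, were chosen after seeing the data.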

Results

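The study measured gene expression in C2C12 cells, an established mouse myoblast line that stops dividing when it is held in suspension. The cells were brought into G0, the reversible resting state outside the cell cycle, by 48 hours in semi-solid methyl cellulose. They were kept there without addition (control) or with purified Wnt3A at 50 ng/ml, a secreted ligand that stabilises β-catenin. Each group had 2 Affymetrix arrays, which the labels call biological replicates. Signals are on a log2 scale, values are given as mean ± SD with n = 2 arrays per group, and a difference is Wnt3A minus control. The number of arrays limits the precision, because a spread taken from 2 arrays is itself uncertain. The median signals of the 4 arrays were between 4.15 and 4.22. Across the tested genes the lowest correlation of a pair of arrays was r = 0.936, between control replicate 1 and Wnt3A replicate 2, and the highest was 0.978, both between control replicate 1 and Wnt3A replicate 1 and between the control arrays; the Wnt3A arrays correlated at 0.957.

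The series title asks for β-catenin gene networks specific to quiescence, and the comparison of Wnt3A with control in G0 cells is the only contrast the labels give. Tnfrsf11b, which encodes osteoprotegerin, a decoy receptor that limits bone resorption, was at 1.26 ± 0.15 in control and 8.13 ± 1.48 with Wnt3A (SD, n = 2). Col8a1, a short-chain collagen gene, was at 3.43 ± 0.97 in control and 8.82 with Wnt3A, where both arrays read 8.82. In the other direction Slpi, a secreted protease inhibitor, was at 10.20 ± 0.22 in control and 5.82 ± 0.12 with Wnt3A, and Cxcl5, a neutrophil chemokine, was at 8.98 ± 0.20 and 4.57 ± 0.54. None of the 9294 genes tested passed an adjusted p of 0.05 in limma with the group as the only term. Unmoderated statistics and the test against a 1.2-fold change also gave 0 genes. Scaling the arrays to their hybridization controls gave 49, and the replicate number as a block gave 83. The labels do not say whether arrays with the same number were paired. With the group as the only term the lowest adjusted p in limma, that of Slpi, was 0.0796. At an unadjusted p under 0.05 there were 528 genes, 229 higher and 299 lower with Wnt3A, where 464.7 are expected by chance.

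By size, 337 genes were at least 2-fold apart with both Wnt3A arrays beyond both control arrays, 143 of them higher and 194 lower with Wnt3A. Among all tested genes 34.4% had groups that did not overlap, where chance gives 33.3%. The other ways to split the 4 arrays into pairs gave 396 such genes when the arrays were split by replicate number and 26 for the crossed split. With 1 array left out the rule sets 1 array against 2 and is met more easily, so such counts cannot be set against 337. The share of higher genes was 42.4% with all 4 arrays and 59.1% without control replicate 2. It was 33.0% without control replicate 1, 50.2% without Wnt3A replicate 1 and 47.1% without Wnt3A replicate 2. With arrays scaled to their hybridization controls, 324 genes were at least 2-fold higher and 108 lower; that scaling moved the median difference of all tested genes from -0.02 to 0.30.

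The genes of lowest p among those 337 did not pass the test over all genes. On the higher side stood Grb14, an adaptor that binds the insulin receptor, with a difference of 4.09 (SE 0.33, 95% confidence interval 3.21 to 4.96, adjusted p = 0.181 in limma). Col8a1 differed by 5.39 (SE 0.49, adjusted p = 0.202) and Tnfrsf11b by 6.88 (SE 0.72, adjusted p = 0.250). Edn1, the gene of the vasoconstrictor peptide endothelin, differed by 2.59 (SE 0.24). The remaining 6 were Prss35 (3.75), Gask1b (2.94), the glycine receptor subunit gene Glrb (2.42), the glutathione transferase gene Gsta2 (2.08), the sterol synthesis gene Msmo1 (1.76) and the somatostatin receptor gene Sstr2 (1.52). On the lower side stood Slpi with -4.38 (SE 0.21, 95% confidence interval -4.93 to -3.83) and Cxcl5 with -4.42 (SE 0.33, adjusted p = 0.181). The asialoglycoprotein receptor gene Asgr1 differed by -4.30 and Crybg1 by -3.04, both with an adjusted p of 0.181. The glutamate transporter gene Slc1a3 (-3.55), the prostaglandin F receptor gene Ptgfr (-3.34), the small proline-rich gene Sprr1a (-2.79), the GDNF receptor gene Gfra1 (-2.28), the mTOR inhibitor gene Deptor (-2.22) and the cathelicidin gene Camp (-2.06) made up the rest. Control means of Tnfrsf11b, Prss35 and Gask1b and Wnt3A means of Slc1a3 and Ptgfr lay under the limit for dim genes, 2.18, so their differences rest on signals near background. Other probe sets of the same gene above that limit gave smaller differences for Tnfrsf11b (3.44) and Col8a1 (2.35), and for Slc1a3 (-1.07), Gfra1 (-0.87) and Deptor (-0.40) at the narrowest.

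**Figure D1:**
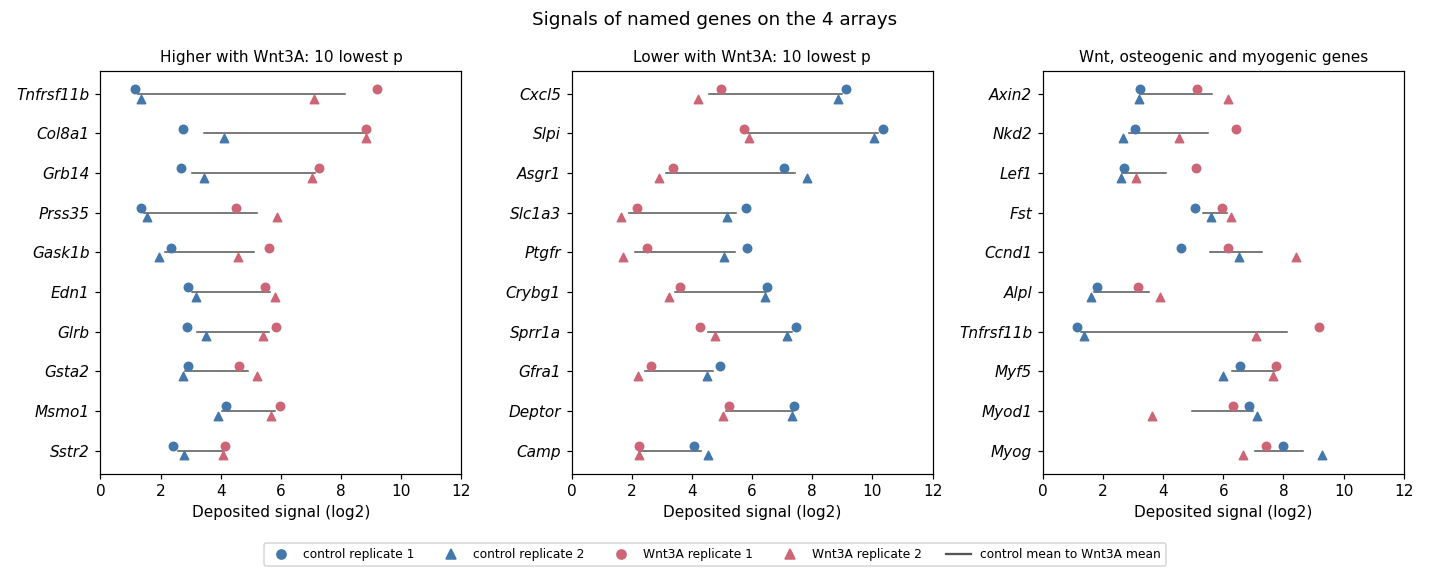
Deposited log2 signals of the 20 genes of lowest p and of Wnt, osteogenic and myogenic genes on the 4 arrays (x axis), with circles for replicate 1, triangles for replicate 2, blue for control and red for Wnt3A; a grey line joins the group means. Tnfrsf11b read 1.15 and 1.36 on the control arrays and 9.18 and 7.09 on the Wnt3A arrays, while the 2 Wnt3A arrays of Lef1 (5.09 and 3.10) and Myod1 (6.32 and 3.62) lay far apart.

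Target genes of canonical Wnt signalling rose as a group. In the list of Wnt feedback and canonical target genes, 8 members were tested, 7 were higher with Wnt3A, and for 6 both Wnt3A arrays lay above both controls. Axin2, a scaffold of the β-catenin destruction complex and a standard readout of the pathway, was at 3.23 ± 0.02 in control and 5.64 ± 0.72 with Wnt3A, a difference of 2.41 (SE 0.38). Nkd2, a feedback inhibitor, was at 2.86 ± 0.28 and 5.48 ± 1.33, a difference of 2.62 (SE 0.66), with Wnt3A arrays at 6.42 and 4.54. Notum, which removes the lipid from Wnt proteins, differed by 0.83 and Apcdd1 by 0.69. The median difference of the list was 0.84 (camera, adjusted p = 9.18e-05; adjusted p = 0.657 with an estimated correlation), and 0.53 without Wnt3A replicate 1. With no filter on dim genes it was 0.23 (adjusted p = 0.0151), so its size depends on the filter. Adjusted over the list alone, Axin2 and Nkd2 passed, with adjusted p in limma of 0.0155 and 0.0474; over all genes theirs were 0.409 and 0.648, and 0 members passed. Lef1, a DNA-binding partner of β-catenin, differed by 1.46 (SE 0.67), and by 0.46 without Wnt3A replicate 1. Nkd1 was under the limit for dim genes in both groups, with a Wnt3A mean of 1.43 ± 0.19, and was not tested.

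The list of other reported β-catenin targets, with 21 genes tested, also rose as a group, with a median difference of 0.35 (camera, adjusted p = 0.000766; adjusted p = 0.657 with an estimated correlation). In 18 of them the difference was above 0; both Wnt3A arrays lay above both controls in 6 and below both in 3. Ccn4, a matricellular protein gene, differed by 0.77 (SE 0.21), Fst, the gene of the activin and myostatin antagonist follistatin, by 0.78 (SE 0.29), Bmp4 by 0.70 and the hyaluronan receptor gene Cd44 by 0.60. Adjusted over the list alone, 0 members passed. Without Wnt3A replicate 2 the median was 0.06 and the call was lost (adjusted p = 0.136); it was 0.68 without Wnt3A replicate 1 and 0.54 without control replicate 2. Ccnd1, the gene of cyclin D1, was at 5.55 ± 1.36 and 7.28 ± 1.61, with arrays at 4.58 and 6.51 in control and 6.14 and 8.42 with Wnt3A. Its difference was 1.73 (SE 0.99, adjusted p = 0.917 in limma). With the replicate number as a block the SE was 0.23 (adjusted p = 0.0368 in limma). Myc differed by 0.45 (SE 0.41), but lay lower with Wnt3A when Wnt3A replicate 2 was left out.

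The 42 tested components of the Wnt pathway had a median difference of 0.06, with 22 higher and 20 lower (camera, adjusted p = 0.230). Ctnnb1, the gene of β-catenin itself, was at 11.58 ± 0.09 and 11.44 ± 0.13, a difference of -0.14 (95% confidence interval -0.58 to 0.30) that was above 0 after scaling to hybridization controls. The ligand genes Wnt4 and Wnt11 differed by 2.76 (SE 0.61) and 1.58 (SE 0.29), the corepressor gene Tle1 by 1.22 and the receptor gene Fzd4 by -1.04; adjusted over the list alone, 0 members passed, with a lowest adjusted p of 0.0655. Without Wnt3A replicate 2 the list passed, with a median of 0.07 (adjusted p = 0.0485). For the 19 tested genes of non-canonical Wnt signalling and planar polarity the median was -0.02 and the mean -0.02, while the direction of the test was up (adjusted p = 0.949). Among them Ptk7 differed by -0.60, Camk2g by -0.38, Nlk by 0.37 and Rac1 by 0.30.

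Genes of the fat cell programme fell. Of 13 tested adipogenic genes, 12 were lower with Wnt3A, and for 9 both Wnt3A arrays lay below both controls. Lpl, which encodes lipoprotein lipase, was at 9.90 ± 1.70 in control and 5.73 ± 1.14 with Wnt3A, a difference of -4.17 (SE 0.96). Ebf1, a transcription factor of early adipogenesis, differed by -2.11 (SE 0.45), the fatty acid carrier gene Fabp4 by -1.32 (SE 0.22) and the desaturase gene Scd1 by -1.08 (SE 0.28). The median difference was -1.08 (camera, adjusted p = 5.06e-06; adjusted p = 0.657 with an estimated correlation), and -0.47 with no filter on dim genes. Adjusted over the list alone 5 members passed, with a lowest adjusted p of 0.0310 for Fabp4; over all genes 0 passed.

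Bone-related genes went both ways. Of 8 tested osteogenic genes, 4 passed when adjusted over the list alone: Tnfrsf11b (adjusted p = 0.00236) and Alpl (adjusted p = 0.0075) were higher, while Dmp1 (adjusted p = 0.0417) and Ogn (adjusted p = 0.0444) were lower. Over all genes none of the 4 passed in limma. Alpl, the gene of tissue-nonspecific alkaline phosphatase, was at 1.71 ± 0.14 and 3.52 ± 0.52, a difference of 1.81 (SE 0.29). Dmp1, a matrix protein gene of osteocytes, differed by -1.15, and Ogn, the gene of the proteoglycan osteoglycin, by -3.62 (SE 1.08). Ogn read 8.47 and 5.27 on the Wnt3A arrays. As a group the list did not shift, with a median of 0.16 (camera, adjusted p = 0.496) that was 0.04 without control replicate 2 and -0.45 without Wnt3A replicate 1. Control signals of Alpl and Tnfrsf11b and Wnt3A signals of Dmp1 lay under the limit for dim genes.

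Genes of muscle differentiation fell as a group. Of 38 tested members of the list, which holds contractile proteins and enzymes of differentiated muscle, 35 were lower with Wnt3A and for 25 both Wnt3A arrays lay below both controls. Mylpf and Myl1, light chains of fast myosin, differed by -1.23 (SE 0.42) and -0.94 (SE 0.30), the Z-disc gene Ldb3 by -1.09 (SE 0.32) and the sarcomeric actinin gene Actn2 by -0.96 (SE 0.30). The median was -0.86 (camera, adjusted p = 1.5e-08; adjusted p = 0.720 with an estimated correlation), and adjusted over the list alone 0 members passed. The size of the shift followed the control arrays: control replicate 2 lay above control replicate 1 by a median of 1.13, and the difference was -0.28 without control replicate 2 and -1.48 without control replicate 1. Each of these leaves 1 control array, so the direction and size are given without a test.

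The 19 tested myogenic regulators did not shift as a list (median -0.12, camera, adjusted p = 0.496). Myf5, a determination factor of myoblasts, was at 6.28 ± 0.41 in control and 7.71 ± 0.08 with Wnt3A, a difference of 1.43 (SE 0.27). Myog, which drives terminal differentiation, was at 8.64 ± 0.90 and 7.04 ± 0.53, a difference of -1.59 (SE 0.51). Myod1 was at 6.98 ± 0.19 in control and read 6.32 and 3.62 on the Wnt3A arrays, a difference of -2.00 (SE 0.91). Id1 and Id3, inhibitors of these factors, differed by -1.03 (SE 0.23) and -1.12 (SE 0.57; -0.28 without Wnt3A replicate 2), and Id2 by 0.18 (SE 0.25), which was below 0 without control replicate 2 or without Wnt3A replicate 2. Adjusted over the list alone 0 members passed, with a lowest adjusted p in limma of 0.0733. Without Wnt3A replicate 1 the list passed in the lower direction, with a median of -0.23 (adjusted p = 0.0180). Pax7, a marker of muscle stem cells, was under the limit for dim genes at 1.92 ± 0.11 and 2.15 and was not tested.

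Cytokine genes fell as a group, led by chemokines. Of 24 tested genes of NF-κB signalling and inflammatory cytokines, 15 were lower with Wnt3A and for 9 both Wnt3A arrays lay below both controls. Beside Cxcl5, Cxcl1 was at 10.06 ± 0.48 and 7.85 ± 0.59, a difference of -2.21 (SE 0.39). Cxcl12 differed by -4.14 (SE 1.01), with control arrays far apart at 8.38 and 5.36. The alarmin gene Il33 went the other way, from 5.48 ± 0.85 to 8.73 ± 0.89, a difference of 3.26 (SE 0.60). Adjusted over the list alone Cxcl5, Cxcl1 and Il33 passed (adjusted p in limma of 0.00152, 0.0274 and 0.0274). The median was -0.25 (camera, adjusted p = 0.0395; adjusted p = 0.720 with an estimated correlation). The call was lost without control replicate 2 (median 0.0020, adjusted p = 0.146) or without Wnt3A replicate 1 (median -0.08, adjusted p = 0.212); the median was -0.64 without control replicate 1 and -0.65 without Wnt3A replicate 2. With the dimmer 50% left out it was -0.49, and with the mean of a gene's probe sets -0.39.

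The 13 tested markers of fibroblasts and mesenchymal cells had a median of -0.33 (camera, adjusted p = 0.0473; adjusted p = 0.657 with an estimated correlation), with 10 lower. Fap, the gene of fibroblast activation protein, differed by -1.65 (SE 0.28) and passed adjusted over the list alone (adjusted p = 0.0308), though its Wnt3A mean of 1.58 lay under the limit for dim genes. The proteoglycan gene Dcn differed by -1.18, the growth factor receptor gene Pdgfra by -1.22 (-0.52 without Wnt3A replicate 2) and Pi16 by -0.78, where another probe set of Pi16 gave 0.07. The call was lost without control replicate 1 (median -0.39, adjusted p = 0.0850) and without Wnt3A replicate 2 (median -0.23, adjusted p = 0.0920), and the median was -0.64 without Wnt3A replicate 1 and -0.15 with no filter on dim genes. Of 8 macrophage and leukocyte markers 4 were higher and 4 lower, with a median of -0.06 (adjusted p = 0.496). Cd14, a coreceptor for bacterial lipopolysaccharide, differed by -1.16 and passed adjusted over the list alone (adjusted p = 0.0306 in limma). Fcgr3 differed by -0.45, Cd68 by 0.28 and Csf1r by 1.03 (0.20 without Wnt3A replicate 2). Other probe sets of Csf1r gave 0.14 and 1.29. The 8 endothelial and epithelial markers had a median of -0.11 and a mean of 0.02 (adjusted p = 0.768), and Krt8 differed by -0.41 (0.19 on its other probe set), Kdr by -0.26, Cldn5 by 0.20 and Krt19 by 0.96, the last below 0 without Wnt3A replicate 2. Fcgr3 and Kdr with Wnt3A and Cldn5 in control were under the limit for dim genes.

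Genes of glycolysis and hypoxia and genes of the unfolded protein response rose as groups, and neither rise was kept without Wnt3A replicate 2. Of 26 tested glycolysis and hypoxia genes 25 were higher, but for 5 of them only did both Wnt3A arrays lie above both controls. The median was 0.49 (camera, adjusted p = 1.54e-05; adjusted p = 0.720 with an estimated correlation) and 0.0021 without Wnt3A replicate 2 (adjusted p = 0.578); it was 0.24 without control replicate 1 and 0.92 without Wnt3A replicate 1. Adm, the gene of adrenomedullin, read 5.34 and 5.98 in control and 6.10 and 7.33 with Wnt3A, a difference of 1.05 (SE 0.49). The transporter genes Slc2a3 and Slc16a3 differed by 0.74 and 0.70, and the kinase gene Pdk1 by 0.60. Each read higher on Wnt3A replicate 2 than on Wnt3A replicate 1: 10.34 against 9.64, 3.38 against 2.68 and 9.51 against 8.79. In control, Slc2a3 (9.63 against 8.85) and Pdk1 (8.77 against 8.34) also read higher on replicate 2, but Slc16a3 (2.10 against 2.57) read lower. Of 30 genes of the unfolded protein response and of ATF4 targets 27 were higher, 4 of them with both Wnt3A arrays above both controls. Their median was 0.36 (camera, adjusted p = 0.00541, or 0.928 with an estimated correlation), but -0.50 without Wnt3A replicate 2. There 1 Wnt3A array stands against both controls, and control replicate 2 lay above control replicate 1 by a median of 0.82. The list median was 0.03 without control replicate 1, 0.82 without control replicate 2 and 1.24 without Wnt3A replicate 1. The cystine transporter gene Slc7a11 differed by 1.37 (SE 0.36), Edem1 by 1.01 and the stress factor gene Atf3 by more (SE 0.64), but by 0.31 without Wnt3A replicate 2; the oxidase gene Ero1a was higher too (SE 0.78), but lay at -0.046 without Wnt3A replicate 2. Adjusted over either list alone 0 members passed. Wnt3A replicate 2 also had the lowest mean signal of the 18 hybridization-control probe sets, which was 7.35 to 7.57 on the other arrays.

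Neither list of cell cycle genes passed the test with the group as the only term. The 32 tested genes of G2/M and mitosis had a median of 0.09 (camera, adjusted p = 0.294) and the 30 genes of DNA replication and G1/S one of 0.00098 (adjusted p = 0.860). With the replicate number as a block the G2/M list passed in the higher direction (camera, adjusted p = 0.0173). Wnt3A minus control was 0.36 within replicate 1 and 0.11 within replicate 2 for that list. Mki67, a marker of cycling cells, was at 4.80 ± 1.66 and 4.71 ± 0.70, with control arrays at 3.63 and 5.97, and lay higher with Wnt3A when control replicate 2 or Wnt3A replicate 1 was left out. Taken as replicate 2 minus replicate 1, the G2/M genes had a median of 0.92, the unfolded protein response 1.15, glycolysis and hypoxia 0.69 and DNA replication genes 0.36, while ribosomal proteins (-0.13) and heat shock genes (-0.14) lay below 0. The G2/M list had a median of 0.70 without control replicate 2 and 0.62 without Wnt3A replicate 1. It was -0.34 without control replicate 1 and -0.24 without Wnt3A replicate 2. Control replicate 2 lay above control replicate 1 by a median of 1.06 for this list, so these medians depend on which array remains. Cenpf differed by 1.90, but by -0.14 on its other probe set, Ect2 by 0.55, Nek2 by -0.49 and Kif11 by -0.47; Rrm2 differed by 1.46 (SE 0.78; 0.41 without Wnt3A replicate 2), Mcm3 by 0.52 (0.22 without control replicate 1), Mcm4 by -0.55 and Mcm7 by -0.48. Of 33 inhibitors of the cycle and genes tied to quiescence 21 were lower, with a median of -0.17 (camera, adjusted p = 0.402). Against random lists of like signal this list passed in the lower direction (adjusted p = 0.0382). In camera it also passed after scaling to hybridization controls (adjusted p = 0.0385), but its median there was 0.15. That median lay above 0 and was low only beside the 0.30 of all genes. The inhibitor gene Cdkn1a was at 10.30 ± 0.25 and 10.28 ± 0.47 and changed direction without control replicate 2 or Wnt3A replicate 1 and on its other probe set (0.15), Cdkn1b differed by 0.35 (SE 0.33; 0.05 without Wnt3A replicate 1) and Cdkn1c by -0.73 (SE 0.69), which was above 0 without Wnt3A replicate 2. The signalling regulator gene Rgs5 read 5.04 and 8.68 in control and 1.72 and 1.47 with Wnt3A, which is under the limit for dim genes. Its difference was -5.27, but -1.89 on another of its probe sets. Pmp22 differed by -1.01, and the Notch effector gene Hey1 was lower too (SE 0.30).

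Other signalling lists did not pass camera. Of 23 genes of the TGF-β and BMP response, 4 passed adjusted over the list alone, each with an adjusted p of 0.0444 in limma. Among these the activin subunit gene Inhba (1.87, SE 0.32), Smad7 (1.27, SE 0.26) and Pmepa1 (0.86, SE 0.19) were higher and Id1 was lower. The median of that list was -0.20 (camera, adjusted p = 0.996; adjusted p = 0.0330 in the lower direction against random lists), but 0.0032 without Wnt3A replicate 2 and -0.06 without control replicate 1. The 18 Notch pathway genes had a median of 0.13 (adjusted p = 0.344) and passed with the dimmer 50% left out (adjusted p = 0.0410). Notch2 differed by 0.67, Numb by 0.54, Hes6 by 1.09 (0.59 without Wnt3A replicate 2), Hes1 by 0.90 (SE 0.40; 0.37 without control replicate 1) and the ligand gene Jag1 by -0.17 (SE 0.21). For 23 immediate early genes the median was -0.06 (adjusted p = 0.794), with Nr4a2 at -1.43, but at -0.16 on its other probe set. Dusp2 lay at -1.22 and Dusp1 at -1.16, and without Wnt3A replicate 2 they lay at -0.60 and -0.49. For 16 interferon response genes the median was -0.10 (adjusted p = 0.329). Among them Ifi35 lay at -0.80, Ifit2 at 0.63 and Irf7 at -0.41, with Rtp4 lower as well (SE 0.38). Of 42 matrix genes 29 were lower and 13 higher, with a median of -0.26 (adjusted p = 0.325; adjusted p = 0.000857 against random lists) that was -0.07 without Wnt3A replicate 2. Col8a1 passed adjusted over that list alone (adjusted p = 0.00683), and Tnc differed by 1.69 and Lamb1 by -0.53; Timp3 was higher (SE 0.31). The 27 genes of the actin cytoskeleton and SRF or YAP targets had a median of -0.05 and a mean of -0.06, while the direction of the test was up (adjusted p = 0.884). There Amotl2 was higher (SE 0.32), and Ccn1 differed by 0.74, Itga5 by 0.41 and Lmod1 by -0.50.

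Genes of lipid synthesis went both ways. Msmo1 and Cyp51, both enzymes of cholesterol synthesis, differed by 1.76 and 1.43 (SE 0.26) and passed adjusted over their list alone (adjusted p = 0.0222 and 0.0357 in limma). Lss differed by 0.57, while Scd1 (-1.08), Elovl6 (-1.35), Fads1 (-0.90), Fads2 (-0.62) and Dhcr7 (-0.52) were lower. The 23 genes of cholesterol and fatty acid synthesis had a median of 0.13 (camera, adjusted p = 0.0957) and passed with every probe set kept (adjusted p = 0.0422). The 34 oxidative phosphorylation genes had a median of -0.06 (adjusted p = 0.450), with Cyc1 at -0.46 (-0.16 without control replicate 2), Atp5a1 at -0.36, Sdha at -0.29 and Ndufa4 at -0.29. The 25 ribosomal protein genes had a median of 0.01 (adjusted p = 0.496), with Rpl22 and Rpl14 at 0.19 and Rpl35 and Rps24 at 0.12. Other probe sets of Rpl22 (-0.59) and Rpl35 (-0.039) were below 0. Rpl14 was below 0 without Wnt3A replicate 1 and Rps24 without control replicate 2; without Wnt3A replicate 2 that list passed in the higher direction (median 0.09, adjusted p = 0.0485). The 33 genes of ribosome biogenesis and MYC targets had a median of -0.15 (adjusted p = 0.0929), with Rrp9 at -0.45, Cad at -0.43, Gnl3 at -0.39 and Hspd1 at -0.33; without Wnt3A replicate 2 the list passed in the lower direction (median -0.18, adjusted p = 0.0494), and likewise with no filter on dim genes (adjusted p = 0.0404). The 27 p53 targets and apoptosis genes had a median of 0.11 (adjusted p = 0.0669), with Pmaip1 at 0.77, Mcl1 at 0.59, Fas at 0.80 (0.29 without control replicate 1) and Ei24 at 0.40, and passed without control replicate 1 (median 0.25, adjusted p = 0.00983) and with no filter (adjusted p = 0.0404). The 30 autophagy and lysosome genes had a median of -0.08 (adjusted p = 0.388), with Gabarapl1 at -1.13, Map1lc3a at -0.80 (-0.23 without Wnt3A replicate 2), Tpcn1 at 0.53 (another of its probe sets at -0.00062) and Ctsd at -0.29. The 18 heat shock and folding genes had a median of -0.04 and a mean of -0.0086, while the direction of the test was up (adjusted p = 0.996), with Hsph1 at -0.79, Hspb1 at 0.37, Hspd1 at -0.33 and Cct3 at -0.23. Scaling to hybridization controls moves the difference of every gene by the same amount, so list medians shift by its construction. All 8 lists that passed camera kept their call under it, with medians of 0.67 for other β-catenin targets and for the unfolded protein response, 0.81 for glycolysis and hypoxia, -0.54 for muscle differentiation, -0.0099 for fibroblast markers and 0.07 for cytokines, where the median of all genes was 0.30.

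**Figure D2:**
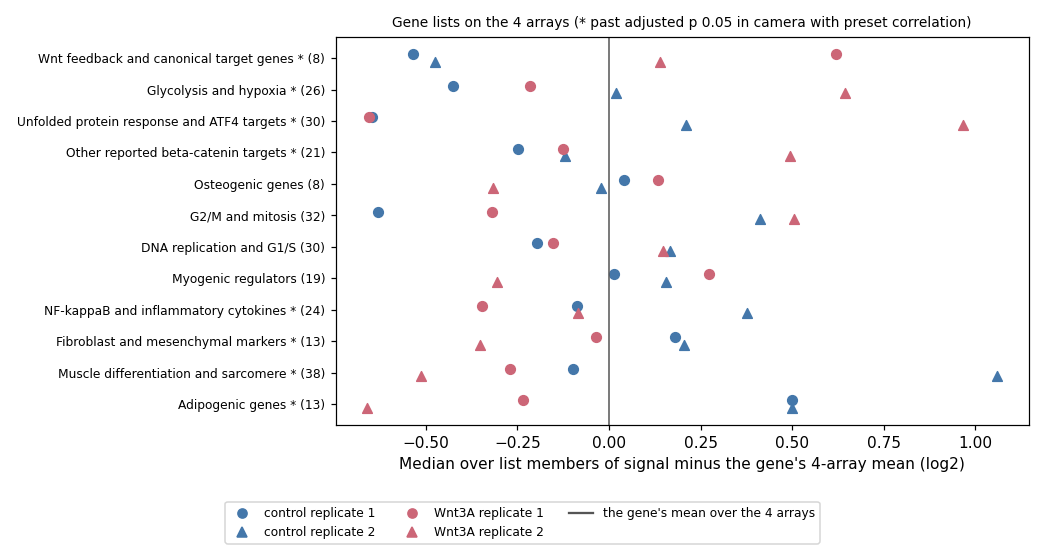
Median over the tested members of each list of the signal minus the gene's mean over the 4 arrays, in log2 units (x axis), for the 8 lists that passed camera with the preset correlation (starred) and 4 that did not; circles are replicate 1, triangles replicate 2, blue control and red Wnt3A. Both control arrays of the adipogenic list lay at 0.50 and its Wnt3A arrays at -0.24 and -0.66, whereas for the unfolded protein response Wnt3A replicate 1 lay at -0.65 beside control replicate 1 at -0.65 and Wnt3A replicate 2 at 0.97.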

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

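Among 1289 probe sets above the limit for dim signals that have no single gene name and entered no comparison, 12 were at least 2-fold higher with both Wnt3A arrays above both controls, and 20 were lower. The widest rise among them was 2.61 on the log2 scale. They stand here because they carry a difference outside the genes that were compared, and no explanation was tested.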

How the results depend on the processing

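Hybridization-control scaling and dim values set to the limit were chosen after seeing the data. In limma no gene passed in the main test; 1 passed at an adjusted p of 0.10, 1 with the dimmer 50% left out (fewer genes tested), 49 with hybridization-control scaling (31 higher, 18 lower) and 83 with the replicate number as a block (38 higher, 45 lower). Of the 83, 77 were among the 337 genes at least 2-fold apart. The labels do not say whether arrays with the same number share a day or culture, so a pairing by design is neither given nor excluded. The differences between replicates 1 and 2 in control and in Wnt3A correlated at 0.478 across genes, which are not independent. The block added G2/M and mitosis to the lists that passed and lost none. The count of 337 became 215 with the dimmer 50% left out, ranged from 314 to 955 with 1 array left out, and was 432 with hybridization-control scaling, where 75% were higher, against 42.4%. With an estimated correlation and with fry 0 of the 8 lists passed. These tests rest on the few degrees of freedom of 4 arrays, so they cannot show that correlated genes undo a call. For the Wnt feedback list the estimated correlation was -0.09, yet its unadjusted p in camera went from 1.22e-05 to 0.0455. Against random lists, which take no account of correlated genes, 11 passed (4 higher, 7 lower): the same 8 and the matrix, TGF-β and quiescence lists. Leaving out 1 array gave medians of the unfolded protein response list from -0.50 to 1.24, reversed without Wnt3A replicate 2; the cause was not tested beyond the array itself. The fibroblast list lost its call in 5 settings: without control replicate 1 or Wnt3A replicate 2, with every probe set kept (adjusted p = 0.0782), with the dimmer 50% left out (0.290) and with dim values at the limit (0.0630). The Wnt feedback, muscle and adipogenic lists kept direction and call in each scaling, and kept direction with each array left out. The Wnt feedback list had too few members with the dimmer 50% left out. Of 142 named tested genes at most 9 changed sign under any setting; in 70 leaving out 1 array moved the difference by over 1.5 times or turned it, in 44 of them when Wnt3A replicate 2 was left out. Pseudocounts were not run, because the values were already logarithms. Signals under 2.18 limit what can be read for dim genes.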

Other observations

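Leaving out each array was planned before the data were examined; its use to weigh the patterns in this part, and each other test here, were chosen after the result was seen. The gene families were chosen by their shared symbols after the differences had been examined. Their camera p-values therefore come from the same data that prompted the choice. Adjustment over the 10 families does not correct for that choice, so these p-values are descriptive and give no independent support. Genes of the insulin-like growth factor axis were lower with Wnt3A as a set: of 11 tested members both Wnt3A arrays lay below both controls in 6, with a median difference of -0.70 (camera, adjusted p = 0.0108 over 10 families; adjusted p = 0.433 with an estimated correlation). Igfbp2, a binding protein gene, differed by -2.48 (SE 0.81), Igfbp4 by -1.48 and the growth factor gene Igf2 by -1.33, while Irs1, a docking protein of the receptor, differed by 1.26. That call was lost without control replicate 1 (median -0.82, adjusted p = 0.0558) and without Wnt3A replicate 2 (median -0.36, adjusted p = 0.128), and the median was -1.15 without Wnt3A replicate 1. Genes of CXC and CC chemokines were lower too (17 tested, median -0.25, adjusted p = 0.000558; adjusted p = 0.430 with an estimated correlation), with the platelet basic protein gene Ppbp at -3.07 (SE 0.49), but 7 of the 17 stand in the cytokine list already. The chemokine call was lost without Wnt3A replicate 1 (median -0.05, adjusted p = 0.119); the median was -0.50 without control replicate 1 and -0.75 without Wnt3A replicate 2.

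Abca8a differed by -4.04 (SE 0.56) and Abca8b by -1.80 (SE 0.23), and the 5 tested genes of the ABCA transporters had a median of -1.22 (camera, adjusted p = 0.0410; adjusted p = 0.430 with an estimated correlation). Abca3 went the other way, by 0.72, and Abca8a and Ppbp lay under the limit for dim genes with Wnt3A. With all 4 arrays the median of the ABCA genes was the value of Abca1, which read 8.78 and 6.59 in control and 8.66 and 4.26 with Wnt3A. The family median depended on the arrays used. It was -0.66 without control replicate 1, -1.93 without control replicate 2, -1.94 without Wnt3A replicate 1 and -0.22 without Wnt3A replicate 2. The apolipoprotein genes Apoe and Apoc1 differed by -3.74 (SE 1.37) and -3.11 (SE 0.70), where Apoe read 7.44 and 3.42 on the Wnt3A arrays. Their family of 8, with a median of -0.11, did not pass camera (adjusted p = 0.138). The median was -0.15 without control replicate 1 and -0.13 without control replicate 2. It was 0.11 without Wnt3A replicate 1 and -0.30 without Wnt3A replicate 2. The family passed with hybridization-control scaling (camera, adjusted p = 0.0086) at a median of 0.21, above 0 but below the 0.30 of all genes. Complement genes were lower (6 tested, median -0.65, adjusted p = 0.0427; adjusted p = 0.430 with an estimated correlation), led by C1ra at -2.02, but not without Wnt3A replicate 1 (median -0.21, adjusted p = 0.164); the median was -0.34 without control replicate 2. Caveolin genes of non-muscle cells, Cav1 and Cav2, were higher by 1.80 (SE 0.35) and 1.78 (SE 0.26), and the muscle caveolin gene Cav3 differed by -1.17 (SE 0.56); the family of 7 did not pass (adjusted p = 0.181), but did without control replicate 2 (0.00538). Semaphorins (adjusted p = 0.181), ADAMTS proteases (0.111), caspases (0.513) and ephrins with their receptors (0.572) did not pass camera either. ADAMTS proteases passed with hybridization-control scaling (camera, adjusted p = 0.0179) at a median of 0.12, above 0 but below the 0.30 of all genes. Their median was -0.20 with all 4 arrays, -0.35 without Wnt3A replicate 2 and -0.07 without Wnt3A replicate 1.

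The arrays part by replicate number as much as by treatment: 396 genes were at least 2-fold apart between the numbers, against 337 between the groups. With 4 arrays there are 3 splits, 2 of which gave at least 337 genes, and the highest of the others gave 396; the splits are too few for a share under 0.05. On both arrays of replicate 2, Malat1 (-3.21), Atrx (-3.37) and Akap9 (-3.17) were lower and Il6 (4.23) and Trib3 (3.20) higher than on those of replicate 1, and the 18S control probe sets read 7.21 and 9.40 against 10.42 and 10.46. RNA degradation in replicates 2 is a candidate explanation; the 3' minus 5' signal of β-actin was 0.16 higher there, a size that neither excludes nor requires it. A shared day, medium or culture stays open as well, since the labels give none of these.

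Much of the rise of glycolysis genes may come from Wnt3A replicate 2: without that array the median was 0.0021, and without control replicate 1 it was 0.24. The median of the unfolded protein response was -0.50 without Wnt3A replicate 2, but also only 0.034 without control replicate 1. So no single array can be named as its carrier. Leaving out Wnt3A replicate 2 sets Wnt3A replicate 1 against both controls. Control replicate 2 lay above control replicate 1 by a median of 0.48 for glycolysis genes and 0.82 for the unfolded protein response. That gap enters the medians without Wnt3A replicate 2. For glycolysis genes Wnt3A minus control was 0.20 within replicate 1 and 0.72 within replicate 2. For the unfolded protein response it was -0.07 and 0.88. With the replicate number as a block, both lists passed in the higher direction (camera with the preset correlation, adjusted p = 1.14e-08 and 7.69e-06). That fit tests the mean over the numbers and not each number by itself, and the labels do not say whether arrays with the same number were paired. A response to Wnt3A that took place in only 1 of the 2 cultures stays open, as does a difference in handling of the cultures.

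The lower muscle list may reflect in part how far control replicate 2 had differentiated. Without control replicate 2 the median was -0.28 and without control replicate 1 it was -1.48, so most of the size depends on which control is used, while the direction does not. Both Wnt3A arrays lay below control replicate 1 as well, by -0.14 and -0.32. Myog, at 9.27 on control replicate 2, was higher than on control replicate 1. An effect of Wnt3A on differentiation and a chance difference between the control cultures cannot be told apart with 2 controls.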
